A study of Mus musculus with 12 samples.

How the data were processed

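The series holds 12 two-colour arrays of mouse oocyte RNA, each with aged RNA in one dye and young RNA in the other. The RNA numbers, dyes and labelling of each array were taken from its labels. Arrays of the same 2 RNAs were counted as 1 replicate, which gave 3 replicates named by the number of the aged RNA.

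The values deposited by the authors were taken as log10 ratios, 1 per probe and array. No source used here states whether they are ratios of the 2 dyes or already aged over young, which is weighed below. Scanner software, background correction, dye normalization and the handling of control spots are not given in the sources used here, and control spots could not be told from other probes. The values were held within -2 and 2: 1215 values lay exactly on these limits, 97.4% of them on the 4 arrays of labelling 1 of pairs 2 and 3, and 513 were exactly 0. Both kinds, 0.638% of all values, were treated as missing, a choice made after seeing them. The array medians on the log10 scale were near 0 in pairs 2 and 3, and in pair 1 they were -0.316 and -0.0799 with the aged RNA in Cy5, and -0.0374 and 0.0473 with it in Cy3. The overall direction of the ratio, the scaling and any centring by the authors stay unknown.

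Both readings of the direction were set against each other in the data. The part of the values that changed sign with the dye swap, which follows the RNA if the values are dye ratios, correlated between 2 probes of one gene at r = 0.164 over 867 genes, above the highest of 1000 shuffles (0.0932, and 0.115 in a separate set). The part that kept its sign correlated at r = 0.0715, below the highest of its shuffles (0.0917), although it agreed between pairs 2 and 3 at r = 0.756. The highest of 1000 shuffles is a strict bound, so agreement between probes in this part is not excluded. The difference between 0.164 and 0.0715 was not tested. In pairs 2 and 3 together the values between probes were 0.121 and 0.0153, and in pair 1 both were 0.164. As deposited, arrays of opposite dyes correlated below 0 in pair 1 (mean r of -0.194) and above 0 in pairs 2 and 3 (0.0937 and 0.170), so in those pairs the part that kept its sign was the larger. On the agreement between probes, which does not separate the readings in pair 1, the values were read as dye ratios and turned to aged over young by the dyes of each array, with Cy5 over Cy3 assumed as the likely direction, and the other reading was kept as an alternative.

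Values were converted to log2, each array was centred on its median, and the arrays with aged RNA in Cy3 had their sign turned. Within each RNA pair the arrays of each orientation were averaged, then both orientations with equal weight, so that a constant dye effect cancels. Probes with the same single gene symbol were averaged, and probes with several genes or none stayed rows of their own without a name. Symbols came from the platform annotation; 4247 of the 4262 single-gene probes had their gene ID in the RefSeq table of GRCm38.p6, and 0 symbols changed. Positions were not given because no source names a genome build.

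The 3 pair values of each row were tested against 0 with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with the data.table package (version 1.17.8), and Benjamini-Hochberg adjustment at 0.05. Differences among pairs and dye effects were tested with limma on all 12 arrays, the first with the dye orientation and the second with the pair in the model. Of 24 gene lists, the 23 with at least 5 measured members were tested by camera with a preset correlation of 0.01 among the 3089 named genes, with an estimated correlation and with fry besides. The lists covered oocyte genes, egg calcium signalling, maternal mRNA storage, DNA methylation, chromatin, energy metabolism, redox genes, meiosis, cell cycle, DNA repair, apoptosis, protein folding and turnover, ribosomes, and markers of cumulus, blood and stromal cells. Psme3ip1, Hspg2 and Hspbap1, which match the name patterns of their lists but not their function, were left out after the data were seen.

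The design, tests, gene lists, first set of alternatives and the rule for named genes were fixed before the data were examined. The exception was the removal of Psme3ip1, Hspg2 and Hspbap1 from their lists. The rule took the 10 highest and 10 lowest named genes past the threshold with 1 sign in the 3 pairs, filled by smallest unadjusted p where fewer passed. It also took up to 4 members of each list by smallest p, 15 genes whatever their values, and the 3 genes with the smallest p in the tests of pair and of dye. The text gives 4 members for the list that passed and for the citrate cycle, and 2 for most others.

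Alternatives covered the centring and scaling of arrays, single labellings and dye orientations, each replicate left out, fits of 12 arrays, robust and unmoderated variances, other thresholds, complete rows, a filter on technical spread in place of one on signal, and other ways to test the lists. Keeping limit values, testing only named rows, counting probes with several genes in the lists, leaving out the labelling 1 arrays of pair 1, reading the values as already aged over young, and an estimated correlation for the lists that passed under an alternative were added after seeing the data.

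The fits were tested on simulated data drawn from the technical spread and the spread between pairs of 20450 rows, with 200 rows changed 1.5-, 2- or 4-fold. With 3 pairs and the observed spread between pairs, the test recovered 0% of rows changed 1.5-fold, 0% at 2-fold and 40.9% at 4-fold, with 0 false calls. With technical spread alone it recovered 31.3% at 2-fold and 97.0% at 4-fold. The block fit of 12 arrays recovered 77.6% at 2-fold, with 141 false calls among 281. The test among pairs recovered 77.3% of 4-fold changes and the dye test 100% of them. A list of 12 genes shifted by -0.5 on the log2 scale was recovered, and 0 other lists passed. The genes were simulated independently of each other, so this cannot show how often lists of correlated genes pass by chance. The shift was also larger than the -0.26 of the real list of ubiquitin-conjugating enzymes. Figures were drawn with matplotlib.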

Results

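RNA from oocytes of aged mice was set directly against RNA from oocytes of young mice on 12 two-colour arrays, which asks how gene expression in the oocyte differs with maternal age. On every array an aged RNA carried one dye and a young RNA the other. The arrays held 3 pairs of RNA: aged RNA 1 with young RNA 1 (pair 1), aged RNA 2 with young RNA 5 (pair 2), and aged RNA 3 with young RNA 2 (pair 3). Each pair was hybridised on 4 arrays, from 2 labellings in both dye orientations, and these 4 arrays were counted as 1 replicate. The labels do not say whether the RNAs came from separate animals, so the p-values measure the spread between these 3 pairs, which may be technical. The table held 22575 probes, of which 4262 had 1 gene symbol, naming 3089 genes; 6822 listed several genes and 11491 had no gene listed here. Spot intensities were not used, so the signal behind each ratio is unknown and the number of arrays limits the precision. All ratios below are log2 ratios of aged over young, relative to the median of each array. Their direction is likely rather than settled, since it takes the deposited values as Cy5 over Cy3, a common convention for two-colour arrays that no source used here states and no value here tests. Reading them as dye ratios at all, rather than as values already turned to aged over young, rests on agreement between probes of one gene, which does not separate the readings in pair 1. The difference in that agreement between the readings was not tested. Correlations between arrays run the other way, since only in pair 1 were arrays of opposite dyes negatively correlated as deposited. With the opposite convention every log2 ratio below changes sign, and the dye called brighter is the other one.

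In the comparison of aged with young oocytes the named gene with the smallest p was Nol9, a nucleolar kinase of ribosomal RNA processing, at 1.85 ± 0.21 (SD, n = 3). Hsp90aa1, the inducible cytosolic chaperone, lay at 1.15 ± 0.39, Aldh4a1, a mitochondrial enzyme of proline breakdown, at 1.22 ± 0.31, and Tmem14a, a membrane protein, at 1.19 ± 0.43 (SD, n = 3 each). Among the genes taken by smallest p, described below, the lowest were Agk, a mitochondrial lipid kinase, at -1.20 ± 0.27, Azi2, an adaptor of innate immune signalling, at -1.06 ± 0.29, and Cxadr, a junctional adhesion protein, at -0.97 ± 0.33. None of these genes passed the test: limma found 0 of 21370 rows, 3089 of them named genes, at an adjusted p under 0.05, and the lowest adjusted p was 0.124.

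At an unadjusted p under 0.05 there were 1400 rows, against 1068.5 by chance, 595 higher and 805 lower in aged oocytes. Among the named genes there were 237, against 154 by chance, 72 higher and 165 lower. All 3 pairs had the same sign in 29.8% of rows and in 32.7% of named genes, where chance gives 25%. The 42.5% share of higher rows among those 1400 depended on the setting, from 26.0% with labelling 2 alone and 31.3% without replicate 3 to 49.8% with labelling 1 alone and 56.8% with aged RNA in Cy3 only. Without centring it was 14.7% of 1242 rows (with the opposite convention 85.3%, and 57.5% with centring), and leaving out the centring moved the median of all rows by -0.11. A fit of all 12 arrays with the pair as a random block called 227 rows, and a fit that took the 12 arrays as independent replicates called 438. In arrays simulated with the observed spread between pairs, 141 of the 281 calls of that block fit were false, so its calls are given as an alternative only. Without replicate 1 the test called 42 rows (35 higher and 7 lower in aged oocytes), without centring 13 (12 higher and 1 lower), and in a refit of named genes alone 1, which was Nol9. Among the genes named above, Nol9, Aldh4a1 and Tmem14a passed without replicate 1 (limma, adjusted p = 0.0026, 0.013 and 0.0090). Nol9 also passed without centring (limma, adjusted p = 0.041).

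Since no gene passed, the genes below were taken by smallest unadjusted p and 1 sign in the 3 pairs, and none of them passed. On the higher side, besides those given, were the prefoldin subunit Pfdn2 at 0.94 ± 0.11, Rab5if at 0.89 ± 0.14, Rbx1, the RING subunit of cullin ubiquitin ligases, at 0.89 ± 0.18, Tpra1 at 0.75 ± 0.08, the nucleoside diphosphate kinase Nme2 at 0.77 ± 0.18, and the nuclear matrix protein Banp at 0.68 ± 0.08 (SD, n = 3 each). On the lower side were the adaptor Crk at -0.88 ± 0.23, Cep120 and Cntln, both centriole proteins, at -0.85 ± 0.24 and -0.85 ± 0.26, the ubiquitin protease Usp38 at -0.84 ± 0.26, Sucla2, a subunit of the citrate cycle enzyme succinate-CoA ligase, at -0.80 ± 0.19, Cryl1 at -0.77 ± 0.15, and Map2k1, a kinase of the MAP kinase pathway that acts in oocyte maturation, at -0.74 ± 0.15. Adjusted p over these 20 genes ran from 0.124 to 0.558 in limma, and 17 of the 20 passed in the block fit of 12 arrays.

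Different probes for one gene often gave different answers. Pfdn2 had one probe at 1.87 and another at 0.02, and the 3 probes of Tpra1 lay at 1.64, 0.49 and 0.11. The Nol9 probe rose and fell over the 12 arrays together with 9 of the other probes of highest ratio, at r over 0.9, and the 3 probes that list Nol9 together with another gene lay between -0.46 and 0.03. Of 19 probes that list one of the 20 genes among several, 7 had the sign of the gene's mean. For Hsp90aa1 such probes reached -1.53. Both probes of Crk, at -1.02 and -0.74, and both of Map2k1, at -0.85 and -0.64, had 1 sign. Across the 867 genes with more than 1 probe, the mean ratios of the first 2 probes correlated at r = 0.164 over genes, which are not independent replicates, and the highest of 1000 shuffles was 0.115 (0.0932 in a separate set of 1000). These 2 probes had the same sign in only 57.0% of the genes, so the sign of a gene measured by 1 probe is uncertain.

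**Figure D1:**
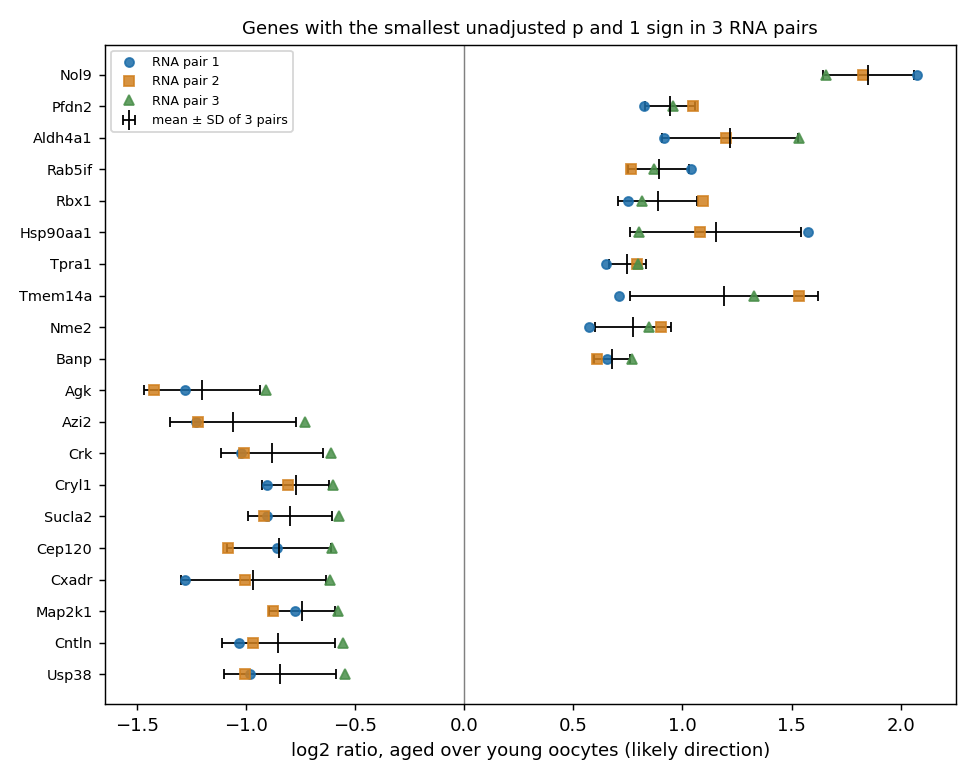
The log2 ratio of aged over young (likely direction) on the horizontal axis for the 20 genes taken by smallest unadjusted p, with a coloured point per RNA pair and a black bar for the mean ± SD of the 3 pairs. Nol9 lies highest at 1.85 and Agk lowest at -1.20, and none of the 20 passed at an adjusted p under 0.05.

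Of 23 gene lists only the ubiquitin-conjugating enzymes, with ubiquitin and its relatives, passed the threshold, lower in aged oocytes than the other named genes with camera at a preset correlation (adjusted p = 0.0148). That call was lost with an estimated correlation (adjusted p = 0.712), with which no list passed. The estimate for this list was -0.06, below the preset 0.01, so the loss cannot be put down to correlation among its members. With an estimated correlation camera takes its degrees of freedom from the 3 pairs alone, so a list can hardly pass. Of 12 measured members 10 had a mean ratio below 0 and 8 lay below 0 in all 3 pairs, with a list mean of -0.27 ± 0.08 (SD, n = 3 pairs). Ube2e3 lay at -0.67 ± 0.21, the ubiquitin-like modifier Sumo2 at -0.88 ± 0.56, Ube2d3 at -0.35 ± 0.26 and Ube2g1 at -0.32 ± 0.19, the last from 3 probes at -1.40, -0.18 and 0.62. No member passed alone, adjusted over all rows or adjusted over the list alone. The mean of the ubiquitin-conjugating enzymes less that of other named genes was -0.26. The call ended without replicate 3 (-0.26, adjusted p = 0.110), with labelling 1 alone (-0.23, adjusted p = 0.0511), with aged RNA in Cy5 only (-0.20, adjusted p = 0.259) or in Cy3 only (-0.31, adjusted p = 0.245). Fry, which tests the list against no change and not against other genes, gave an adjusted p = 0.159. With the values read as already aged over young no list passed, and the lowest adjusted p = 0.892.

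The lists of energy metabolism lay mostly below 0 without passing. In the citrate cycle list 4 of 5 measured members were below 0, with a mean of -0.28 ± 0.02 (SD, n = 3 pairs) and a camera adjusted p = 0.122, and 4 members passed adjusted over the list alone, against 0 over all rows. These were Sucla2, given above, Pdhb, a subunit of pyruvate dehydrogenase, at -0.57 ± 0.12, the aconitase Aco1 at -0.47 ± 0.23, and Suclg2, another subunit of succinate-CoA ligase, at 0.43 ± 0.17. Of 15 members of oxidative phosphorylation 8 were below 0, with Sdha, of respiratory complex II, at -0.86 ± 0.41 and Atp5b, of ATP synthase, at -0.67 ± 0.33, and a camera adjusted p = 0.479. Mitochondrial import and dynamics had 9 of 13 members below 0, among them the fusion proteins Opa1 at -0.44 ± 0.06 and Mfn1 at -0.46 ± 0.27, with an adjusted p = 0.122. The mitochondrial ribosome had 8 of 10 below 0, with Mrps31 at -0.35 ± 0.12 and Mrpl44 at -0.44 ± 0.34, and an adjusted p = 0.201. Glycolysis and glucose transport had 7 of 11 below 0, with Aldoc at -0.50 ± 0.24 and Ldha at 0.30 ± 0.28, and an adjusted p = 0.515. Antioxidant and redox genes had 7 of 12 above 0, with Txnip at -0.23 ± 0.21 and Gpx7 at -0.36 ± 0.59, and an adjusted p = 0.865. In none of these other lists did a member pass, adjusted over all rows or adjusted over the list alone. Tested by fry for change in either direction, the citrate cycle and mitochondrial import lists both gave an adjusted p = 0.0286 and the proteasome list 0.0153, a test that does not set a list against other genes.

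Among the lists of protein folding and turnover, 16 of 22 heat shock proteins and chaperonins lay below 0, with a mean of -0.27 ± 0.29 (SD, n = 3 pairs). The pair means were -0.52, 0.04 and -0.32, and the camera adjusted p = 0.0577. Hsp90aa1, given above, and the chaperonin subunit Cct2, at -0.61 ± 0.09, passed adjusted over the list alone, in opposite directions. The endoplasmic reticulum stress list had 4 of 8 below 0, and its adjusted p = 0.192. Pdia4, a disulfide isomerase, at -0.79 ± 0.39, and Hsp90b1, the chaperone of that compartment, at -0.80 ± 0.48, passed adjusted over the list alone. The proteasome had 8 of 12 below 0, with Psmb2 at -0.63 ± 0.24 and Psma1 at -0.43 ± 0.26, and an adjusted p = 0.385. The heat shock, endoplasmic reticulum stress and proteasome lists passed without replicate 2, with adjusted p = 2.34e-06, 0.0169 and 0.0169. With an estimated correlation and without replicate 2 none of these lists passed (adjusted p = 0.836 each). That test then rests on pairs 1 and 3 alone and could hardly pass a list. With all 3 pairs the estimated correlations of these lists were 0.144, 0.130 and 0.230, above the preset 0.01. The preset may thus give them too small a p-value. The heat shock list also passed with labelling 2 alone (adjusted p = 0.0426), in the block fit (0.0153), with 1 probe per gene (0.0327), with probes listing several genes counted (0.0451) and without the labelling 1 arrays of pair 1 (0.0457). The first and last of these settings rest pair 1 on its labelling 2 arrays, among them the array of widest spread (SD 1.23, aged RNA in Cy3). With an estimated correlation these heat shock calls ended, with adjusted p = 0.943, 0.815, 0.661 and 0.847 for labelling 2, 1 probe per gene, several-gene probes and without those arrays; the block fit was not run with one. The heat shock list had an adjusted p = 0.367 without replicate 1 and 0.382 without replicate 3. With probes listing several genes counted the mitochondrial ribosome list passed too (0.0237; adjusted p = 0.661 with an estimated correlation). The cytosolic ribosome had 14 of 23 below 0, with Rpl37a at 0.72 ± 0.31 and Rpl4 at -0.51 ± 0.35, and an adjusted p = 0.515. The probes of Rpl4 ran from -1.08 to -0.01.

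The lists of meiosis and the cell cycle did not pass with all arrays and 3 pairs. Cohesin, synapsis and recombination had 12 of 16 members below 0, with Wapl, which releases cohesin from chromosomes, at -0.91 ± 0.37 and Msh4 at -0.41 ± 0.43, and a camera adjusted p = 0.118. The spindle and kinetochore list had 12 of 18 below 0, with the tubulin Tubb4b at 0.71 ± 0.20 and the centrosome protein Pcnt at -0.55 ± 0.12, and an adjusted p = 0.122. The spindle list passed with labelling 2 alone (adjusted p = 0.0426) and without the labelling 1 arrays of pair 1 (0.0457), but with an estimated correlation the adjusted p = 0.943 and 0.847. Both settings rest pair 1 on its labelling 2 arrays, and the one with aged RNA in Cy3 had the widest spread of all arrays (SD 1.23). With labelling 1 alone the spindle list had an adjusted p = 0.510. M-phase kinases and cyclins had 8 of 17 above 0, with Map2k1 passing adjusted over the list alone and Cdk1, the kinase that drives entry into M phase, at -0.67 ± 0.64. That list had an adjusted p = 0.865, a mean of 0.0043, and a median and a test below 0. DNA repair had 14 of 24 below 0, with Rad23b at -0.43 ± 0.13 and Topbp1 at -0.66 ± 0.50, and an adjusted p = 0.479. Apoptosis regulators had 7 of 10 above 0, with Bik at -0.28 ± 0.06 and Bad at 0.37 ± 0.34, and an adjusted p = 0.479.

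In the DNA methylation and imprinting list 7 of 12 members were above 0 (adjusted p = 0.515). Dppa3, a maternal-effect gene that protects the maternal genome from demethylation, lay at 0.62 ± 0.20. Dnmt1, the maintenance DNA methyltransferase, lay at -0.63 ± 0.41 from 3 probes at -1.02, -0.90 and 0.01, and the de novo methyltransferase Dnmt3b at 0.23 ± 0.18 from probes at 0.16, 0.70 and -0.17. The chromatin list had 17 of 27 above 0 (adjusted p = 0.645), with the histone chaperone Nap1l1 at -0.44 ± 0.26 and the histone methyltransferase Ezh2 at -0.30 ± 0.11, from probes at -0.06 and -0.54. The chromatin remodellers Atrx and Smarca4, named whatever their values, lay at 0.16 ± 0.25 and at -0.01 ± 0.15, and Smarca4 changed sign when arrays were scaled to one spread. The probes of Atrx ran from -0.17 to 0.48 and those of Smarca4 from -0.22 to 0.27. No member of either list passed, adjusted over all rows or adjusted over the list alone.

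Of 9 measured oocyte and maternal-effect genes 6 lay above 0, and the list had a median of 0.08, a mean of -0.10 and a test above 0, with an adjusted p = 0.878. Dppa3 and Kit, the receptor of oocyte growth, at -0.70 ± 0.36, passed adjusted over the list alone. Bmp15, a growth factor secreted by the oocyte, lay at -0.31 ± 0.48. Egg calcium signalling and fertilization had 6 of 10 below 0, with Trpm7 at -0.35 ± 0.25 and Atp2b1 at 0.46 ± 0.49, and an adjusted p = 0.385. Maternal mRNA storage and decay had 11 of 16 below 0, with the deadenylase subunit Cnot8 at -0.43 ± 0.22 and the cap-binding protein Eif4e at -0.36 ± 0.16, and an adjusted p = 0.479. The probes of Eif4e had opposite signs, at 0.10 and -0.82. Of 15 genes to be named whatever their values 6 had a probe of their own.

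Neither tested list of markers of other ovarian cells passed, with 7 measured members in each. Cumulus and granulosa cell markers had 6 of 7 members below 0, with Inhbb at -0.15 ± 0.14 and Cyp11a1 at -0.09 ± 0.07, an adjusted p = 0.515, and pair means of -0.11, -0.08 and -0.0032. Gja1, the gap junction protein, lay at 0.09 ± 0.39 and had the opposite sign without centring. Blood and immune cell markers had 5 of 7 above 0, with the antigen-presentation gene H2-Aa at 0.36 ± 0.12, Csf1r at 0.17 ± 0.10 and an adjusted p = 0.385. Of the stroma and endothelium list only Pecam1 was measured, at -0.15 ± 0.15, and that list was not tested.

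**Figure D2:**
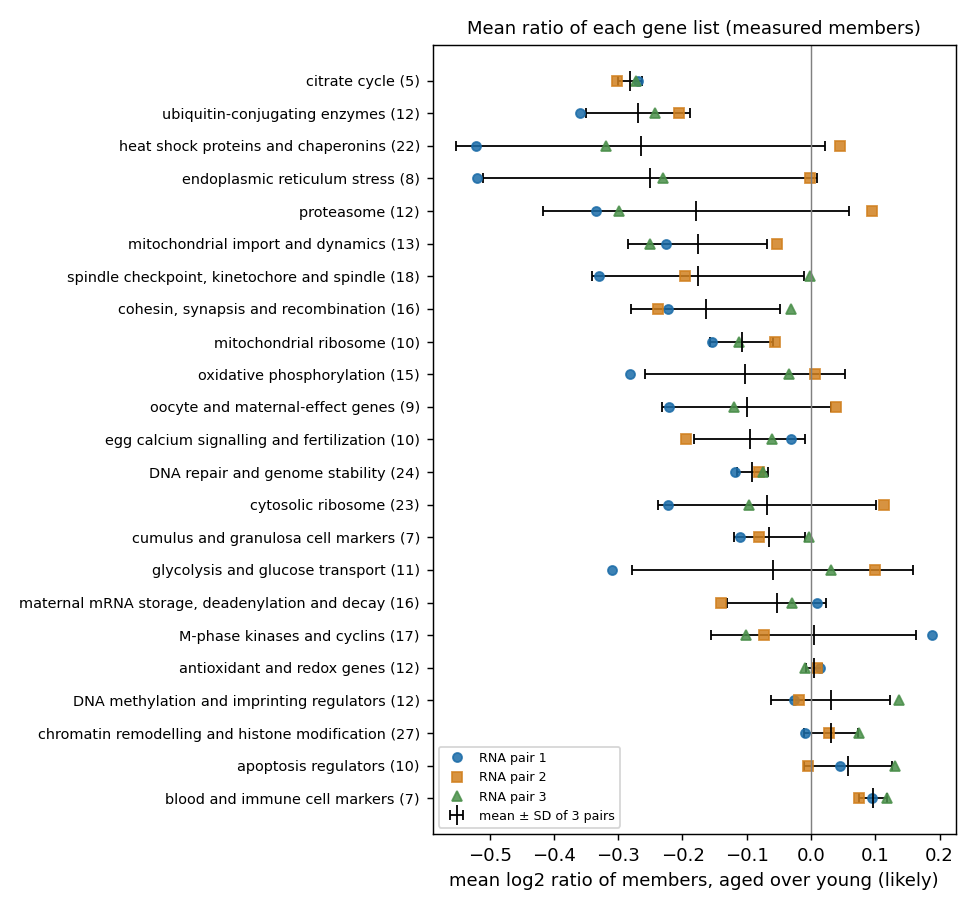
The mean log2 ratio of aged over young (likely direction) of the measured members of each of 23 gene lists, with a coloured point per RNA pair, a black bar for the mean ± SD of the 3 pairs, and the number of measured members in parentheses. The list of ubiquitin-conjugating enzymes lies at -0.27, and the heat shock list has pair 2 at 0.04 and pairs 1 and 3 at -0.52 and -0.32.

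The ratio itself differed among the 3 RNA pairs for 1236 of 21402 rows (5.78%) in limma's F test against the technical spread of the 12 arrays, among them 151 named genes. Pcp4l1 lay at 2.18 in pair 1, 0.08 in pair 2 and -0.23 in pair 3 (adjusted p = 0.000639). Zp2, a protein of the egg coat, lay at -1.69, 0.56 and -2.41 (adjusted p = 0.00106), and the sialyltransferase St3gal6 at -1.88, 0.45 and -1.496 (adjusted p = 0.00154). This test compares these RNA pairs, not ages. It takes 1 technical variance for all arrays, though those of pair 1 spread more widely, with SDs over probes of 0.79 to 1.23 against 0.39 to 0.77. Without the dye term in the model 659 rows passed.

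Many probes had a part of their value that kept its sign across the dye swap, read here as a dye effect; if the values were already aged over young, it would not be one. This term passed for 4908 rows (22.9%), 2496 with more signal in Cy5 and 2412 with more in Cy3 if the values are Cy5 over Cy3, and for 563 named genes. The median size of the term was 0.23 on the log2 scale. The named genes with the smallest p were the sorting nexin Snx5 at -0.74, 4930506C21Rik at -1.004 and the interferon gamma receptor Ifngr1 at -0.85, as log2 of Cy5 over Cy3 (likely), with adjusted p = 0.00445, 0.00445 and 0.00449. Their aged over young ratios were 0.05 ± 0.39, 0.09 ± 0.27 and 0.26 ± 0.27, the Snx5 sign turning without centring or with scaling and that of 4930506C21Rik without centring. Without centring 3643 rows passed, 609 with more signal in Cy5 and 3034 with more in Cy3, or the reverse with the opposite convention.

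Arrays of one RNA pair and dye orientation correlated across probes at a mean r of 0.490 (6 comparisons), and arrays of one pair with opposite dyes, as deposited, at 0.0235 (12 comparisons). That mean joins opposite signs: r ran from -0.309 to -0.0621 in pair 1, from 0.0332 to 0.228 in pair 2 and from 0.106 to 0.275 in pair 3 (4 comparisons each), so that the arrays of pairs 2 and 3 did not reverse as a whole with the dye swap. By Spearman rho pair 1 ran from -0.0605 to 0.0846. Between pairs, arrays of the same orientation correlated at 0.238 and arrays of opposite orientation at 0.136 (24 comparisons each). After averaging the dye orientations, the ratios of the 2 labellings of a pair correlated at r = 0.690, 0.548 and 0.289 for pairs 1, 2 and 3. Between pairs the correlation was 0.183 for pairs 1 and 2, 0.0670 for pairs 1 and 3, and 0.158 for pairs 2 and 3. The ratios of pair 1 spread more widely, with an SD over probes of 0.66 against 0.32 and 0.31. These correlations run across probes, which are not independent replicates.

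**Figure D3:**
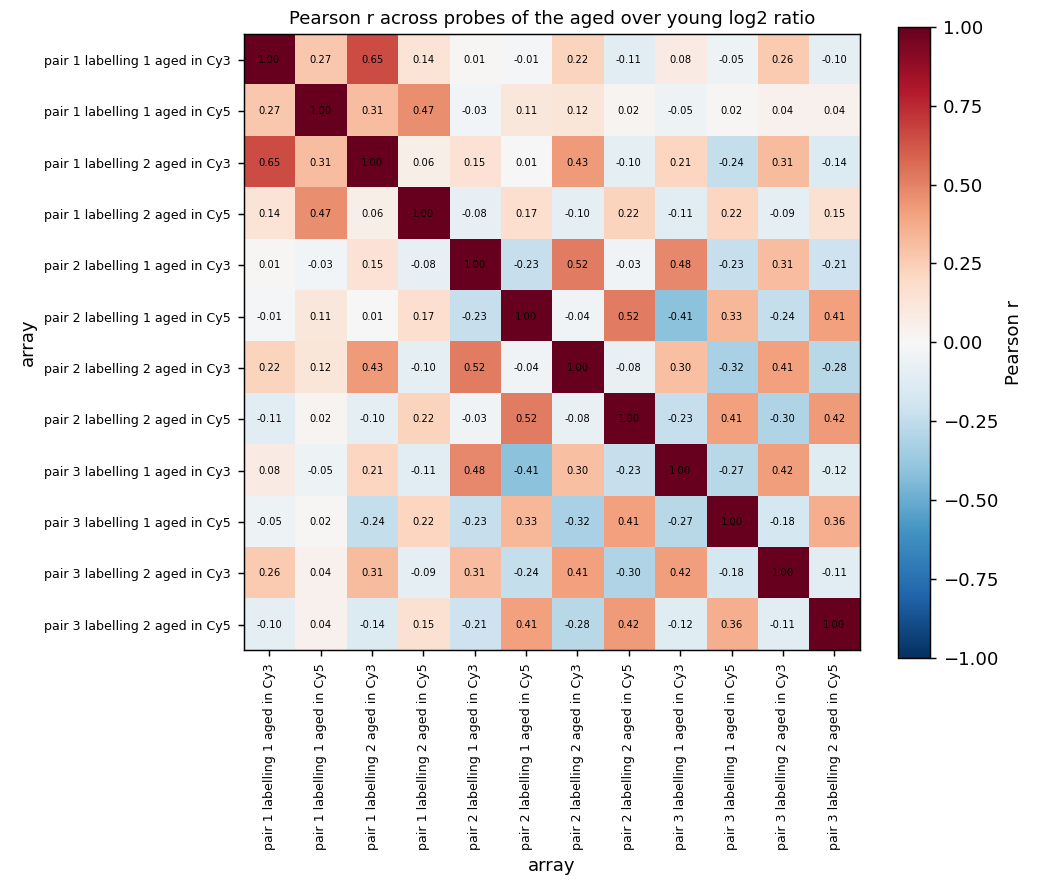
Pearson r across probes between the aged over young log2 ratios of each array on both axes, ordered by RNA pair, labelling and dye, with colour from -1 (blue) to 1 (red). Arrays of one pair and dye orientation have the highest mean r, at 0.490. In pair 3 these values, 0.420 and 0.364, lie below the highest between pairs 2 and 3, 0.482. Arrays of one pair with opposite dyes once turned to aged over young run from 0.0621 to 0.309 in pair 1 and from -0.275 to -0.0332 in pairs 2 and 3.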

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

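Alternatives that kept limit values, tested only named rows, counted probes with several genes in the lists, left out the labelling 1 arrays of pair 1, read the values as already aged over young, or joined an estimated correlation to another setting were chosen after seeing the data. Spot signal over background was not used, so its limit on dim genes is unknown. The cause of the changes below was not tested unless stated.

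The count of genes differing between aged and young oocytes, 0 of 21370, was also 0 under 18 other settings, leaving out replicate 2 or 3 among them. The thresholds on adjusted p among the 18, the loosest at 0.10, could give no other count, since the lowest adjusted p in limma was 0.124. The count was 13 without centring, 227 with 12 arrays and the pair as a random block, 438 with 12 arrays as independent replicates, and 1 with only named rows fitted and tested, which changed both the variance estimates and the adjustment. Leaving out replicates gave 0 to 42, the 42 without replicate 1. All 227 rows of the block fit were among the 438. The count of lists, 1, was 3 with labelling 2 alone, 2 in the block fit, 2 with 1 probe per gene, 3 with probes listing several genes counted, and 3 without the labelling 1 arrays of pair 1. It was 0 with labelling 1 alone, with aged RNA in Cy5 only, with aged RNA in Cy3 only, with an estimated correlation, with fry (a test against no change, not against other genes), and with the values read as already aged over young. Without one replicate it ran from 0 to 4. The test among pairs gave 659 rows without a dye covariate against 1236 with it.

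For 76 single genes over 1058 results under alternatives, 29 came past the threshold, 25 of them in the block fit, and 21 turned sign. Without centring Gja1 was -0.020, Snx5 -0.064 and 4930506C21Rik -0.026. With arrays scaled to one spread Smarca4 was 0.058 and Snx5 -0.027, and with labelling 2 alone Smarca4 was 0.0051. With aged RNA in Cy5 only Txnip was 0.20, Ube2g1 0.062, Cnot8 0.068, Gja1 -0.14, Snx5 -0.69, 4930506C21Rik -0.92 and Ifngr1 -0.59. In such arrays the dye effect does not cancel. With aged RNA in Cy3 only Cyp11a1 was 0.13, Csf1r -0.20 and Smarca4 0.12. Without one replicate Smarca4 ran from -0.056 to 0.074, Pcp4l1 from -0.071 to 1.13, Snx5 from -0.18 to 0.19, 4930506C21Rik from -0.069 to 0.17 and Gja1 from -0.039 to 0.32.

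None of the 21 list calls under alternatives that were tested again with an estimated correlation passed. That test takes its degrees of freedom from the few RNA pairs alone, so it could hardly pass a list. It therefore cannot show that correlation among members undid these calls. The estimates from all 3 pairs lay above the preset 0.01 for heat shock (0.144), endoplasmic reticulum stress (0.130) and proteasome (0.230). They did so too for spindle (0.209) and the mitochondrial ribosome (0.108), but not for the ubiquitin-conjugating enzymes (-0.06). For the lists above it, the preset may give too small a p-value. For the 23 lists over 435 results, 17 turned sign, as the mean of members less that of other named genes. M-phase kinases were -0.032 with labelling 1 alone and -0.018 with complete rows. With labelling 2 alone egg calcium signalling was 0.015 and maternal mRNA storage 0.0040. With aged RNA in Cy5 only the mitochondrial ribosome was 0.045 and glycolysis 0.058, and with it in Cy3 only blood markers were -0.014, DNA repair 0.014 and redox genes -0.023. Redox genes were -0.026 with limit values kept. DNA methylation was -0.016 with 1 probe per gene, and with probes listing several genes counted cumulus markers were 0.0017, DNA methylation -0.0057 and redox genes -0.014. Without one replicate the cytosolic ribosome ran from -0.16 to 0.019, glycolysis from -0.14 to 0.075 and M-phase kinases from -0.078 to 0.085. With the sign of every ratio turned, 43.1% of rows in place of 56.9% lay above 0.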

Other observations

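The tests of high probes and of agreement between pairs, the list counts among genes that differ between pairs, and the choice of genes in the next paragraph were made after the results were seen; the regroupings of arrays were planned.

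Genes past the test among RNA pairs fell mostly into 2 kinds. Of the 151 named genes, pair 1 stood apart from the other two in 95, pair 2 in 50 and pair 3 in 6. Among all rows past the test with a value in each pair, the counts were 937, 265 and 32. The ratios of pair 1 had an SD over probes of 0.66, against 0.32 and 0.31, while the test takes 1 technical variance for all arrays. Wider spread alone could thus set pair 1 apart, which was not tested. Below 0 in pairs 1 and 3 and higher in pair 2 were the chaperones Hspa8, at -2.25, 0.02 and -1.84 in pairs 1, 2 and 3, Hspa4, at -1.22, 0.08 and -1.44, and Hspb1, at -0.99, 0.34 and -1.24. The lysosomal lipase Lipa, at -1.80, 0.34 and -1.99, the translation regulator Paip2, at -2.36, -0.27 and -1.99, and Cdk1, at -1.17, 0.05 and -0.89, were also highest in pair 2, as was Zp2. Plat, tissue plasminogen activator, was the reverse, at -0.46, -2.17 and -0.40. High in pair 1 alone were the phosphatase subunit Ppp2ca, at 2.41, 0.20 and -0.15, the actin-capping protein Capzb, at 1.90, 0.17 and -0.29, and Cdk4, at 2.23, 0.16 and -0.39. The heat shock list held 4 genes past the test among pairs (Hspa8, Hspa4, Hspb1 and Dnajc7) among 22 members, against 4.89% of all named genes. It did not pass over 23 lists (Fisher's exact test, one-sided, adjusted p = 0.464).

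A group of 18 probes had a mean log2 ratio of 1.5 or more and a ratio above 0 in all 3 RNA pairs, with a median of 1.98, or 3.95-fold, and 17 of them were above 0 on every array with a value. Only 4 probes met the same bound below 0. A constant dye effect cancels in this mean by design. The lowest mean in either dye orientation was 1.13, and the median of the lower of the pair 2 and pair 3 ratios was 1.72. Every probe was thus high in both orientations, and the median probe also in pairs 2 and 3. A choice by a mean of 1.5 or more favours such probes. These values therefore cannot decide on a signal in one orientation or on the wide spread of pair 1 as a cause. Of the 18, 15 had no gene listed and 3 named Nol9, Pfdn2 and Tpra1, while the 7 other probes that list those genes lay between -0.46 and 0.49 with a median of 0.019, so these probes may bind a sequence other than the gene listed. Which RNA they bind, and an age difference in that RNA, stay open and untested, since probe sequences were not used.

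With the values read as dye ratios, the ratios agreed little between RNA pairs; read as already aged over young, the pairs would correlate at r = 0.269, 0.342 and 0.756, and what follows would not apply. If the pairs had the same true ratios, the agreement of the 2 labellings would give an r of at least 0.564 between any 2 pairs, but the highest was 0.183. This argues against noise that is independent between labellings as the only cause. Technical error shared by the arrays of 1 pair would raise the agreement of its labellings too, so the comparison cannot address it. Aged and young labels exchanged in 1 pair would make its r with both others negative, if the pairs shared an age signal. The lowest r was 0.0670, but the pairs shared so little, with a highest r of 0.183, that this cannot decide the question. Different amounts of cumulus or granulosa cells cannot be told apart from other differences between the RNAs: 0 of 7 measured markers passed the test among pairs, but Has2, Ptx3 and Amh had no probe of their own. Differences between the animals or oocyte collections behind each RNA stay open and untested.

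Turning the sign of each RNA pair gives 4 patterns, too few for a share under 0.05. The real pattern gave 0 genes and the highest other 0, so all 4 were as large, and for lists the real pattern gave 1 and the highest other 5, with 2 of 4 as large. Among 100 groupings of the 12 arrays into 3 sets of 4, the real pairs included, only that 1 gave as many as 1236 rows, and the highest other gave 767. Among 100 splits into 2 sets of 6, only the real dye split, 1 of them, gave 4908 rows, and the highest other gave 88.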
